A study of Mus musculus with 40 samples.

How the data were processed

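Liver RNA of 20 male mice was measured by RNA sequencing. The labels list 40 samples, 2 sequencing lanes for each mouse, and the tables have 1 column per mouse, so the mouse was the replicate (n = 10 per group). How the lanes were merged is not stated in the labels. Per the labels' protocols, RNA was purified with a DNase step, and libraries were made with a stranded total RNA kit that removes ribosomal RNA and read in pairs, although the labels give the molecule as polyA RNA. Per the submitters' processing notes the genome build was GRCm39. The aligner, the counting program and the treatment of reads that map to several genes are not given in the sources used here.

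The authors deposited raw counts per protein-coding gene, which are whole numbers and differ in their total between mice, and these were used for all main tests. The authors also deposited FPKM values (fragments scaled to gene length and depth) that they rounded to whole numbers, so these were treated as a score without a fixed scale and used for alternatives alone. Of the rounded values 43.3% were 0, and 23.4% of the values whose count was above 0 were 0, so rounding removes the low genes. The 21500 gene identifiers were matched to a mouse gene name table, which named 21457. The 43 unnamed identifiers held 0.0078% of the counts, and 3647 genes had no count in any mouse. The reference annotation at hand was of another build, so it gave names and no coordinates. No column of per-mouse values was left unmapped.

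Total counts per mouse were 20994073 to 27456678 in CDAA-HFD mice and 18467060 to 26078285 in BLT1i mice. Genes under 1 CPM carry a wide counting error at this depth. All 90 pairs of mice within a group differed by more than sampling noise (chi-square per degree of freedom from 6.34 to 32.09), so none was counted as a repeat of another. The mice are separate animals per the labels, and no cage, batch or order of collection is stated there. The titles also carry a number after the letter S, which the labels do not explain. It runs in a separate block for each group, as the mouse numbers do. Any effect that follows this order cannot be told apart from treatment.

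Genes were filtered with filterByExpr, which left 13993, scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F-test, two-sided) in R 4.3.3, without covariates. Adjusted p is Benjamini-Hochberg over the tested genes with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F, and confidence intervals cover 95%. CPM are TMM-scaled and given as mean ± SD. For 51 gene lists fixed before the data were examined, the score of a mouse was the mean log2 CPM (prior count 2) of the tested members. The difference of group means was tested by a permutation test over mice (100000 resamples, two-sided) with Benjamini-Hochberg adjustment over the 49 lists that had at least 3 tested members. Counts adjusted over the list alone use the members' edgeR p values. Set tests with camera, with a preset correlation of 0.01 or an estimated one, and fry were run in limma 3.58.1. The adjusted p with an estimated correlation is that of camera over the 49 lists. Camera compares a list with the other genes, whereas the permutation test does not.

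The groups, the tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule named the leukotriene genes Ltb4r1, Ltb4r2, Alox5, Alox5ap and Lta4h, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with at least 1 CPM in either group, up to 3 members with the lowest p of each list (2 where the list did not pass), and the markers Col1a1, Col3a1, Acta2, Timp1, S100a8, Adgre1, Trem2 and Clec4f. Predicted genes without a proper name were counted and not named; 14 of the called genes were of this kind. Further list members named in the text were chosen after their values were seen, to show members that passed against the list's name or did not pass.

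The gene test was checked on simulated counts with the means and library sizes of these mice. For BLT1i against CDAA-HFD alone, over 13956 simulated genes, it recovered 90 of 100 genes changed by 0.5 on the log2 scale and 97 of 100 changed by 1, with 5 false among 192 calls. Of 3 simulated lists moved by 0.5, 3 were recovered, and 1 of 43 lists without a moved member was called. The simulated genes were drawn independently, whereas members of the real lists are correlated. Most called list differences were also smaller than 0.5, so the recovery of lists says little about power for the real ones.

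Alternatives were RLE, upper-quartile and total-count scaling, no filter beyond 1 count, a filter of 1 CPM in at least 10 mice, DESeq2 1.42.0, limma-voom with a weight per mouse, limma-trend on log2 of the rounded FPKM plus 1 or 0.1 with and without a filter on low values, 1 surrogate variable from sva 3.50.0, thresholds of 0.1 and 0.01, each mouse left out in turn, and for lists camera, fry, z scores and a prior count of 0.5. After seeing the data, 3 were added: leaving out mice 36 and 72, which lay farthest from the rest on principal components 4 and 3, the immediate early score as a covariate, and lists without members that more than 1 list holds. Control livers without the diet and other doses were not analysed here. The results of some single genes are not reported here.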

Results

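Liver RNA was sequenced from 20 male C57BL/6J mice, 10 in each of 2 groups. All mice had eaten CDAA-HFD, a choline-deficient, amino acid defined diet with 60% of its energy as fat and 0.1% methionine, which is used to induce steatohepatitis and liver fibrosis. They started the diet at 8 weeks of age. After 4 weeks, 1 group stayed on the diet alone (CDAA-HFD mice, numbered 31 to 40 in the labels). The other received the same diet with a compound named BLT1i at 90 mg/kg for 8 weeks (BLT1i mice, numbered 71 to 80). The titles of these samples also carry the code L_286, which the labels do not explain. Livers were taken at 20 weeks of age. The labels do not expand BLT1; the name generally stands for the leukotriene B4 receptor 1, encoded by Ltb4r1, through which leukotriene B4 attracts neutrophils and other leukocytes. The study asked what inhibition of BLT1 does in this model. Total counts per mouse ranged from 20994073 to 27456678 in the CDAA-HFD mice and from 18467060 to 26078285 in the BLT1i mice. Mice without fibrosis or on a control diet were not analysed here, so each value compares 2 groups on the same fibrogenic diet.

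The lists of genes that the xenobiotic receptors CAR and PXR control and of fatty acid oxidation genes that PPAR-alpha controls were higher in livers of BLT1i mice than of CDAA-HFD mice, with 12 of 24 and 21 of 25 members passing as higher. The serum amyloid A genes Saa1, Saa2 and Saa3 were lower. Collagen genes were lower as a list, with 3 of 16 members passing singly, and this call was lost with an estimated correlation in camera (adjusted p = 0.165). Cyp3a11, the main inducible hepatic Cyp3a enzyme of mice, rose 2.70-fold, from 2053 ± 216 to 5547 ± 557 CPM (counts scaled to library size; SD, n = 10 per group; adjusted p = 1.63e-13). Cyp4a14, a fatty acid omega-hydroxylase, rose 5.08-fold from 157 ± 75.4 to 796 ± 184 CPM (adjusted p = 2.84e-06). Saa2, an acute phase protein, fell to 0.593 of its level, from 41.8 ± 8.19 to 24.8 ± 3.64 CPM (adjusted p = 9.18e-05). In all, 788 of 13993 tested genes passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of at most 0.05), 511 higher and 277 lower with BLT1i, and most of the changes were small. The median fold was 1.21 among the genes that rose and 0.842 among those that fell, and 34 genes changed by 2-fold or more, 29 of them higher and 5 lower. The balance of higher and lower genes depended on the scaling. Genes higher with BLT1i numbered 443 and genes lower with BLT1i 401 under upper-quartile scaling, and there were 391 higher and 540 lower with library totals alone. With the score of immediate early genes as a covariate, an alternative chosen after seeing the data, 101 genes passed. Of the 78 named genes with a call 58 then lost it, among them Saa2, Serpina1e, Col8a1 and Egr1 (adjusted p = 0.335, 0.377, 0.217 and 0.135). Egr1 is itself a member of that score, as are Nr4a1, Jun, Zfp36 and Atf3, which also lost their calls. Over the 788 genes the median ratio of the log2 fold changes with to without the covariate was 0.956, while their median SE went from 0.061 to 0.107. The count of lower genes was 171 without CDAA-HFD mouse 33 and 168 without BLT1i mouse 79.

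The 2 largest rises, among genes with at least 1 CPM in either group, were in genes with low counts in the CDAA-HFD mice. Gucy2c, the guanylate cyclase receptor for guanylin peptides in the intestine, rose 12.3-fold from 0.244 ± 0.140 to 3.05 ± 1.02 CPM (log2 fold change 3.62 ± 0.24, SE, n = 10 per group; adjusted p = 2.6e-10). Duox1, an NADPH oxidase, rose 6.08-fold from 0.179 ± 0.128 to 1.12 ± 0.231 CPM. The other 8 of the first 10 were Cyp4a14, Cyp2c29, Cyp2c55, Ppp1r3g, Cyp3a59, Cyp4a10, Cyp4a31 and Egr1, with folds between 5.08 and 2.82. Ppp1r3g encodes a glycogen-targeting phosphatase subunit. Among genes with a proper name and at least 1 CPM in either group, Serpina1e, an alpha-1-antitrypsin gene, fell most, to 0.358 of its level (467 ± 206 to 167 ± 80.3 CPM; adjusted p = 0.00864). It was followed by Serpina12, which encodes vaspin (0.442 of its level), Tmem28, Ttbk1 and Thrsp, a lipogenic gene that responds to carbohydrate (0.502, adjusted p = 0.0112), and then by Cfap44, Derl3, Mfsd4b5, Saa2 and S1pr5. With the immediate early covariate the log2 fold change of Tmem28 turned to 0.12 (adjusted p = 0.926). The call of S1pr5 (adjusted p = 0.0306) was lost without any one of mice 31, 33, 34, 72, 74, 76, 77 and 78, with an adjusted p of up to 0.0630. Members of the Cyp2c, Cyp3a, Cyp4a, Ces, Acot, Mup, Saa and Serpina1 families have near-identical copies, and how the authors' counting divided shared reads is not given in the sources used here, so values of single members are uncertain.

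**Figure D1:**
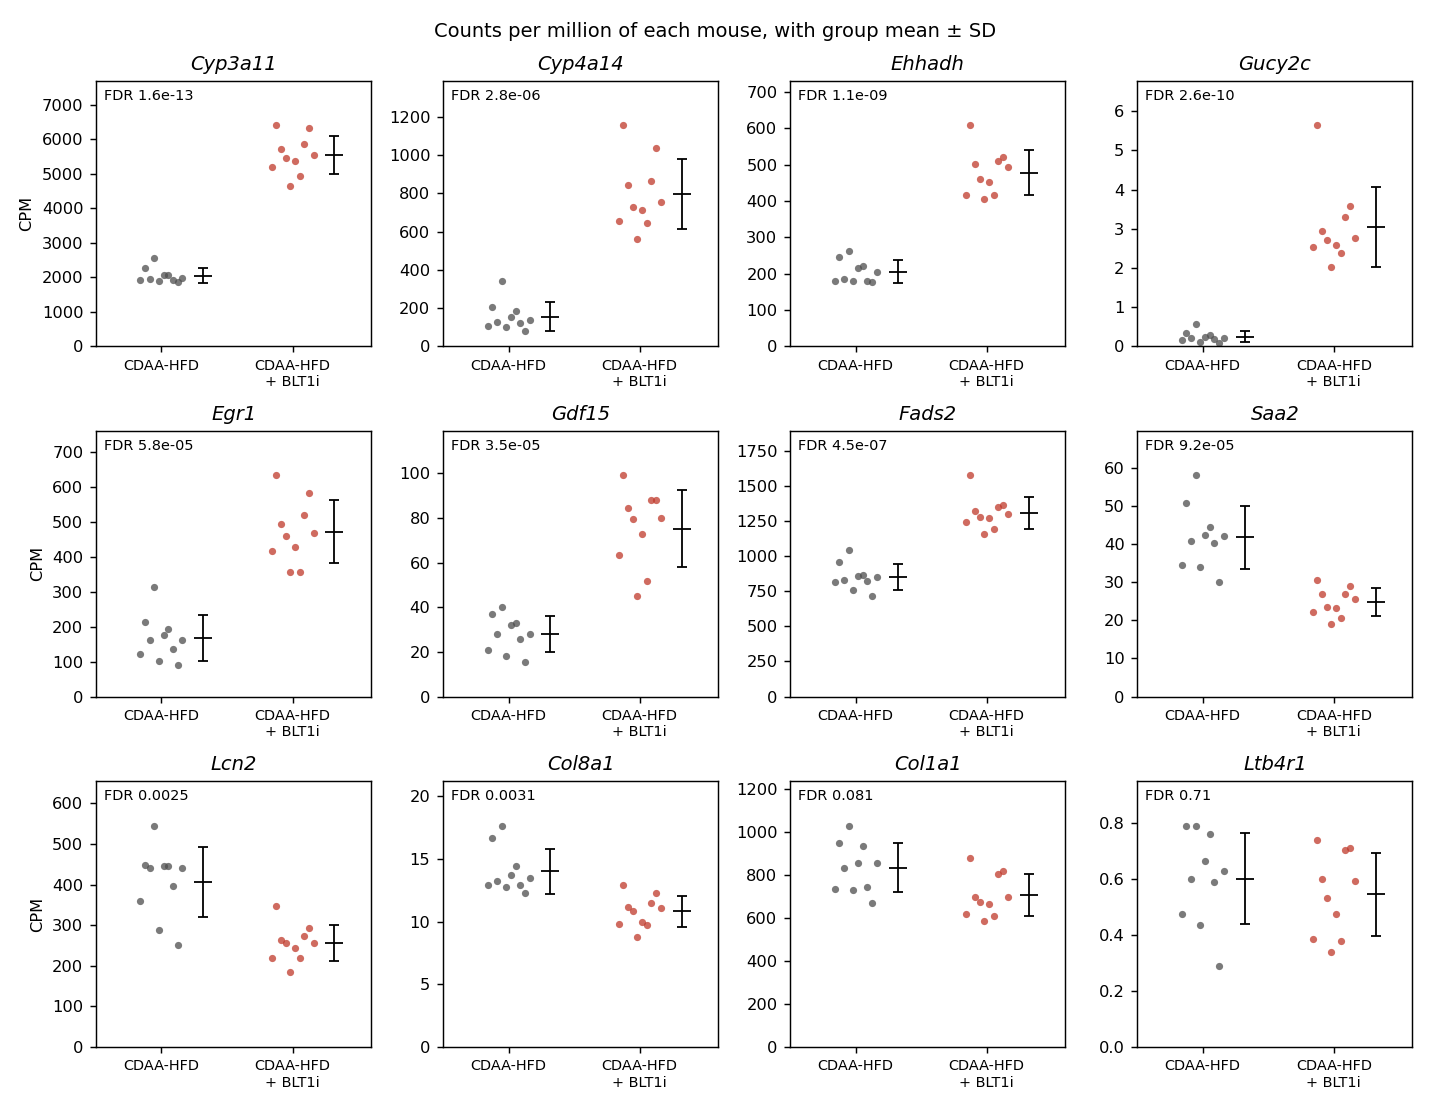
CPM (counts scaled to library size, linear axes from 0) of 12 genes in each mouse; points are mice, the bar beside them is the group mean with its SD (n = 10), and FDR is the adjusted p of the edgeR test. The groups do not overlap for Cyp3a11, Cyp4a14, Ehhadh, Gucy2c, Egr1, Gdf15 and Fads2, while Ltb4r1 lies at 0.602 and 0.546 CPM on average and the groups overlap.

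Genes of fatty acid oxidation that PPAR-alpha controls rose together. Of the 25 tested members of this list, 21 rose, 1 fell and 3 did not pass (23 higher and 1 lower adjusted over the list alone). The mean log2 CPM of the list was higher by 0.66 ± 0.07 (SE, n = 10 per group; 95% confidence interval 0.51 to 0.81; permutation test, adjusted p = 0.00049). The score of all 10 BLT1i mice lay above that of every CDAA-HFD mouse. Ehhadh, the peroxisomal bifunctional enzyme, rose 2.33-fold (205 ± 31.2 to 478 ± 61.9 CPM), Cyp4a31 3.12-fold and Acaa1b, a peroxisomal thiolase, 1.91-fold (353 ± 71.9 to 674 ± 70.5 CPM). The mitochondrial enzymes Cpt2 and Acadm rose by 0.32 ± 0.05 and 0.34 ± 0.05 on the log2 scale (SE). The member that fell was Ucp2, a mitochondrial uncoupling protein found also in macrophages, at -0.20 ± 0.05. Its call was lost without mouse 34 or mouse 79 (adjusted p up to 0.0522), and without mice 36 and 72 (adjusted p = 0.0582). Ppara itself did not pass (0.24 ± 0.08, adjusted p = 0.0869), nor did Angptl4, at 114 ± 33.6 and 113 ± 19.6 CPM.

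The list of genes that the xenobiotic receptors CAR and PXR control was also higher, by 0.64 ± 0.07 (SE, n = 10 per group; 95% confidence interval 0.50 to 0.77; permutation test, adjusted p = 0.00049). Again all 10 BLT1i mice lay above every CDAA-HFD mouse, as they did for the immediate early genes. Of its 24 tested members 12 rose and none fell (17 higher and none lower adjusted over the list alone). Cyp2c55 rose 3.80-fold (4.90 ± 0.953 to 18.5 ± 4.98 CPM), Cyp2c29 4.82-fold and Ces2a, a carboxylesterase, 2.36-fold (24.2 ± 4.30 to 57.3 ± 7.42 CPM). The list members Cyp2b9 and Cyp2b13 varied widely between mice and did not pass, at 1.14 ± 0.34 and 1.42 ± 0.44 on the log2 scale (edgeR adjusted p = 0.0608 and 0.0656). Calls of the PPAR-alpha and xenobiotic lists held with an estimated correlation in camera (adjusted p = 0.0202 and 0.000638). Targets of another xenobiotic sensor, the aryl hydrocarbon receptor, did not pass as a list (-0.04 ± 0.03, adjusted p = 0.389), with Ugt1a6a at -0.12 ± 0.06 and Tiparp at -0.08 ± 0.05.

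**Figure D2:**
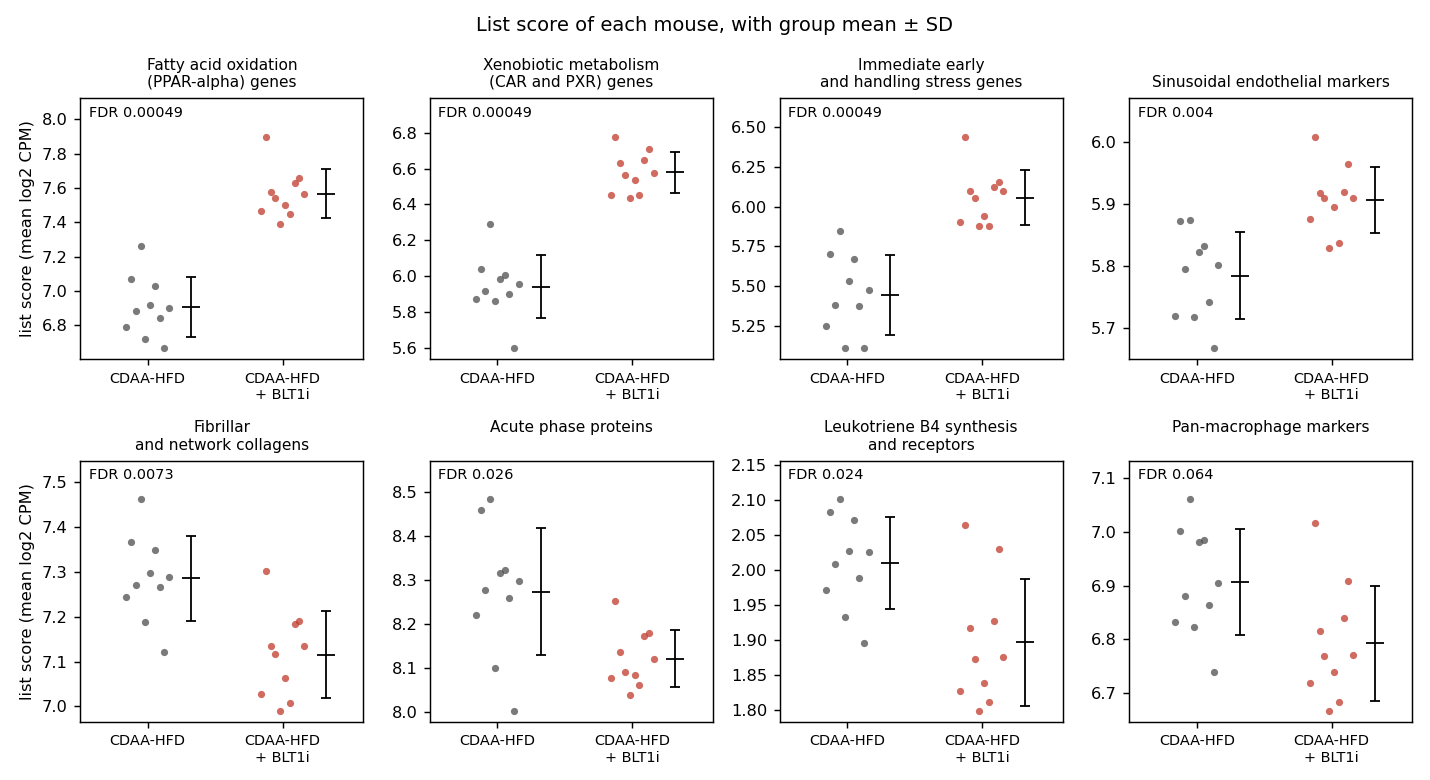
Score of 8 gene lists (mean log2 CPM of the tested members) in each mouse; points are mice, the bar beside them is the group mean with its SD (n = 10), FDR is the adjusted p of the permutation test over mice, and axes do not start at 0. All 10 BLT1i mice lie above every CDAA-HFD mouse for the PPAR-alpha, xenobiotic and immediate early lists, while the groups overlap for collagens, leukotriene genes and macrophage markers.

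Genes of lipid droplets and lipid uptake were higher by 0.22 ± 0.04 (SE, n = 10 per group; permutation test, adjusted p = 0.000735; adjusted p = 0.103 with an estimated correlation). Of 21 members 5 rose and 1 fell (9 higher and 1 lower adjusted over the list alone). Mgll, which cleaves monoacylglycerol, rose 1.42-fold, the lipid droplet protein Cidec 1.63-fold and Fitm2 1.32-fold, while lipoprotein lipase (Lpl) fell to 0.858. Fatty acid synthesis genes split in both directions. Of the 18 tested members of the SREBP1 list 5 rose and 4 fell (5 and 5 adjusted over the list alone). The score differed by 0.04 ± 0.06 (adjusted p = 0.709) while the median log2 fold change was -0.05. The desaturases Fads2 and Fads1 rose 1.53-fold and 1.33-fold (adjusted p = 4.45e-07 and 3.22e-06), as did Me1, Acacb and Elovl5. Thrsp, Tkfc, Scd2 and Pklr fell. The call of Pklr was lost without any one of 14 mice (31, 33, 34, 35, 37, 38, 39, 73, 75, 76, 77, 78, 79 and 80; adjusted p up to 0.106) and with RLE scaling. Fasn and Scd1 gave -0.22 ± 0.14 and -0.05 ± 0.25 with adjusted p of 0.399 and 0.943. Bile acid synthesis and transport genes were higher by 0.11 ± 0.04 (adjusted p = 0.0236; adjusted p = 0.165 with an estimated correlation), 5 of 18 members higher and 1 lower (7 and 1 adjusted over the list alone). Cyp8b1, which directs synthesis to cholic acid, rose 2.00-fold from 96.5 ± 20.1 to 193 ± 50.8 CPM, the transporters Abcc4 and Abcb4 rose 1.25-fold and 1.16-fold, and Cyp2c70 fell by 0.39 on the log2 scale. The call of this list was lost without BLT1i mouse 72 (adjusted p = 0.0558) and with library totals alone (adjusted p = 0.0704).

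Collagen genes were lower as a group with BLT1i. The list of 16 fibrillar and network collagens differed by -0.17 ± 0.04 in mean log2 CPM (SE, n = 10 per group; 95% confidence interval -0.26 to -0.08; permutation test, adjusted p = 0.00729; adjusted p = 0.165 with an estimated correlation). The scores of 5 BLT1i mice lay below every CDAA-HFD mouse. The immediate early score differed between the same groups by 0.61 ± 0.10. No member rose, 3 fell and 13 did not pass, whereas 11 were lower and none higher adjusted over the list alone. Col8a1, a short-chain collagen of vessels and scars, fell to 0.773 of its level (14.0 ± 1.78 to 10.8 ± 1.27 CPM, adjusted p = 0.00306), and Col4a2, a basement membrane chain, to 0.903 (adjusted p = 0.0182). Col6a2 fell to 0.843 (adjusted p = 0.0453), a call lost without any one of 11 mice (31, 33, 34, 35, 36, 39, 71, 72, 73, 78 and 79; adjusted p up to 0.0943). The main scar collagens did not pass singly. Col1a1 had 832 ± 114 and 704 ± 97.7 CPM (log2 fold change -0.24 ± 0.08, adjusted p = 0.0809), and Col3a1 had 1041 ± 78.3 and 932 ± 108 CPM (-0.16 ± 0.06, adjusted p = 0.128).

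The list of matrix crosslinking and remodelling enzymes was lower, with a score difference of -0.09 ± 0.03 (SE, n = 10 per group; permutation test, adjusted p = 0.0415; adjusted p = 0.184 with an estimated correlation). Of 19 members 1 was lower (3 adjusted over the list alone). It was lysyl oxidase (Lox), at 0.839 of its level (adjusted p = 0.0475), and Adamts2, Loxl1 and Timp1 gave -0.20 ± 0.06, -0.20 ± 0.07 and -0.27 ± 0.10 without passing. The calls of the list and of Lox were each lost without any one of 13 mice. For the list these were mice 32, 33, 34, 36, 37, 39, 40, 71, 72, 73, 76, 77 and 79 (adjusted p up to 0.0821). For Lox they were mice 32, 33, 34, 36, 39, 40, 71, 72, 73, 74, 75, 76 and 79 (up to 0.0917). Non-collagen matrix proteins did not pass (-0.09 ± 0.04, adjusted p = 0.0884), and Sparc gave -0.14 ± 0.05. Elastin (Eln) fell to 0.824 (adjusted p = 0.0331), a call lost without any one of mice 32, 34, 35, 40, 72, 73, 78, 79 and 80 (up to 0.0643). Myofibroblast markers were at -0.01 ± 0.05 (95% confidence interval -0.11 to 0.10, adjusted p = 0.93), with Acta2 at 19.9 ± 3.28 and 20.3 ± 4.32 CPM. Among them Tagln, a smooth muscle actin-binding protein, rose 1.18-fold (adjusted p = 0.0133) and S100a6 fell to 0.785 (adjusted p = 0.0319, lost without any one of mice 33, 37, 39, 71, 73, 74 and 79, up to 0.0684). Quiescent stellate cell markers as a list were higher by 0.12 ± 0.03 (adjusted p = 0.0167; adjusted p = 0.177 with an estimated correlation). Of 13 members 1 passed (2 adjusted over the list alone). Vipr1, a receptor for vasoactive intestinal peptide, rose 1.25-fold, with Hhip at 0.69 ± 0.24 and Ngfr at 0.15 ± 0.06. The call of this list was lost with library totals alone (adjusted p = 0.0872). The TGF-beta list did not pass, with a mean difference of 0.09 ± 0.05 (adjusted p = 0.177) and a median log2 fold change of -0.05 (2 higher, or 2 higher and 3 lower adjusted over the list alone). Ccn1 rose 2.01-fold, and Tgfb1 gave -0.16 ± 0.05.

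Of the leukotriene genes, 1 changed, and it was not the receptor. The receptor gene Ltb4r1 (ENSMUSG00000046908) had 0.602 ± 0.164 CPM in CDAA-HFD mice and 0.546 ± 0.148 CPM in BLT1i mice (SD, n = 10 per group; log2 fold change -0.16 ± 0.19, SE; 95% confidence interval -0.56 to 0.24; adjusted p = 0.714; log2 fold change -0.10 without mouse 73). A difference within that interval was not excluded. Alox5ap, which presents arachidonic acid to 5-lipoxygenase, fell to 0.828 of its level, from 25.3 ± 2.12 to 20.9 ± 2.50 CPM (edgeR adjusted p = 0.0114), lower in all 10 BLT1i mice than the CDAA-HFD median. Ltb4r2, Alox5 and Lta4h did not pass (log2 fold changes -0.18 ± 0.14, -0.08 ± 0.18 and -0.05 ± 0.04). The list of 10 leukotriene genes was lower, with a score difference of -0.11 ± 0.03 (permutation test, adjusted p = 0.0242; adjusted p = 0.177 with an estimated correlation), with 1 member lower over all genes tested and 2 adjusted over the list alone. The call of the list, Leukotriene B4 synthesis and receptors, was lost without mice 36 and 72 (adjusted p = 0.0529). Despite its name the list also holds the cysteinyl leukotriene genes Ltc4s, Cysltr1 and Cysltr2. A lower score is therefore not the same as less leukotriene B4 synthesis or fewer receptors. The second member that was lower adjusted over the list alone was Cyp4f18, a hydroxylase of neutrophils that inactivates leukotriene B4. Cyp4f18 gave -0.29 ± 0.09 (adjusted p = 0.0565). It passed in the edgeR test without any one of mice 31, 36, 75 and 78, which makes the count 2. Cysltr1 gave -0.14 ± 0.09.

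Among leukocyte markers, no list fell, and neutrophil genes had few counts. The 15 pan-macrophage markers differed by -0.11 ± 0.05 (SE, n = 10 per group; 95% confidence interval -0.21 to -0.02; permutation test, adjusted p = 0.0639, or 0.0294 with library totals alone). Of these 1 fell (3 adjusted over the list alone), Fcer1g, at 0.862 of its level (adjusted p = 0.0391). Its call was lost without any one of 12 mice (31, 33, 34, 36, 39, 71, 72, 73, 76, 77, 78 and 79; adjusted p up to 0.0822). Cd68 gave -0.17 ± 0.06 and Adgre1, which encodes F4/80, -0.12 ± 0.06 (adjusted p = 0.0791 and 0.304). Lipid-associated macrophage markers did not pass (-0.08 ± 0.06, adjusted p = 0.334), with Lpl lower and Trem2 at 89.0 ± 7.83 and 78.5 ± 7.09 CPM (adjusted p = 0.0504). The list of resident Kupffer cell markers was higher by 0.28 ± 0.10 (adjusted p = 0.0387; adjusted p = 0.341 with an estimated correlation), a call kept in 4 of 10 alternatives. No member passed over all genes and 1 did adjusted over the list alone, Clec4f, at 32.5 ± 10.1 and 52.6 ± 20.7 CPM (adjusted p = 0.0675). Id3 and Vsig4 gave 0.19 ± 0.08 and 0.36 ± 0.15, the latter 0.22 without mouse 79. The Kupffer call was lost without any one of 13 mice (31, 33, 34, 35, 36, 40, 72, 73, 76, 77, 78, 79 and 80; adjusted p up to 0.0722). Neutrophil markers differed by -0.03 ± 0.11 (adjusted p = 0.897), with S100a8 at 1.92 ± 0.397 and 1.69 ± 0.505 CPM (log2 fold change -0.18, or -0.09 without mouse 72) and Cxcr2 at 1.61 ± 0.449 and 1.23 ± 0.269 CPM. The 1 member that fell was Lcn2, which hepatocytes also make in the acute phase.

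Monocyte markers did not pass as a list (0.04 ± 0.05, adjusted p = 0.625), with a median log2 fold change of -0.04 and a negative direction in camera and fry. Of 12 members 1 rose and 2 fell (1 and 3 adjusted over the list alone), Nr4a1 rising 2.42-fold and Ace falling to 0.816. Nr4a1 is also a member of the immediate early list, and with that score as a covariate its log2 fold change turned to -0.08 (adjusted p = 0.934). The score contains Nr4a1 itself, so this value cannot show whether Nr4a1 changed apart from the score. Dendritic cell and antigen presentation genes differed by -0.03 ± 0.05 (adjusted p = 0.772), with Clec9a at 0.19 ± 0.06 and Zbtb46 at 0.09 ± 0.05. T cell markers differed by 0.03 ± 0.12 (adjusted p = 0.897; median log2 fold change -0.06, with the opposite direction in fry). Cd8a rose 1.63-fold from 1.95 ± 0.423 to 3.21 ± 0.990 CPM (adjusted p = 0.0105), and Pdcd1 gave 0.71 ± 0.27. NK cell and cytotoxic markers (-0.02 ± 0.09, with Tbx21 at -0.31 ± 0.16 and Eomes at 0.44 ± 0.23, which passed at 0.68 without mouse 39) and B cell and plasma cell markers (0.12 ± 0.09, or 0.07 without mouse 34, with Sdc1 at 0.14 ± 0.06) had adjusted p of 0.897 and 0.36. Mast cell, basophil and eosinophil markers as a list were higher by 0.17 ± 0.04 (SE, n = 10 per group; adjusted p = 0.0042; adjusted p = 0.165 with an estimated correlation). Of 15 listed genes 3 could be tested, and the 1 that rose, Kit (1.16-fold), is also expressed by other cells. Siglecf and Gata2 gave 0.16 ± 0.09 and 0.15 ± 0.11. The call of this list was lost without any one of mice 35, 72, 73, 75, 77 and 80 (adjusted p up to 0.825), with differences between 0.03 and 0.09. The gene filter was rerun without each mouse, so these losses can reflect a changed set of tested members rather than the mouse itself. Chemokines (-0.03 ± 0.07, adjusted p = 0.832), cytokines and inflammasome genes (-0.04 ± 0.04, adjusted p = 0.611) and interferon-stimulated genes (0.02 ± 0.15, median log2 fold change -0.003, adjusted p = 0.929) did not pass as lists. Pycard and Casp4, both parts of inflammasomes, fell to 0.808 and 0.813 of their levels and Cxcl14 to 0.845. Casp4 lost its call without any one of mice 34, 36, 71, 72, 73, 78 and 79 (adjusted p up to 0.0692), and Cxcl14 without any one of mice 33, 36, 37, 71, 73, 76, 77 and 79 (up to 0.0769). Adjusted over the list alone, 1 chemokine was higher, Cxcl1 (0.255 ± 0.088), and 2 were lower, and of the cytokines and inflammasome genes 1 was higher, Il1a (0.236 ± 0.082), and 4 were lower. Ccl9, Iigp1 and Usp18 gave -0.21 ± 0.07, 0.17 ± 0.09 and 0.25 ± 0.15.

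Among structural cells of the liver, the list of sinusoidal endothelial markers was higher by 0.12 ± 0.03 (SE, n = 10 per group; permutation test, adjusted p = 0.00402; adjusted p = 0.103 with an estimated correlation). Of 15 members 4 rose and none fell (9 higher and 1 lower, Stab1, adjusted over the list alone). Kdr, a VEGF receptor, rose 1.16-fold (adjusted p = 0.00344), the lectin Clec4g 1.17-fold (adjusted p = 0.00954) and Oit3 1.15-fold (adjusted p = 0.0316). The call of Oit3 was lost without any one of mice 31, 33, 34, 35, 71, 72, 73, 78, 79 and 80 (adjusted p up to 0.0671). Vascular and capillarised endothelial markers did not pass (0.03 ± 0.03, adjusted p = 0.519), with Cdh5 and Cldn5 at 0.13 ± 0.05 and 0.16 ± 0.06. Cholangiocyte and ductular markers did not pass (-0.13 ± 0.07, adjusted p = 0.125). Prom1 fell to 0.81 and Anxa4 to 0.923. The call of Anxa4 was lost without any one of 13 mice (33, 34, 35, 36, 38, 39, 40, 71, 72, 73, 76, 79 and 80; adjusted p up to 0.107). The list of hepatocyte identity genes was higher by 0.18 ± 0.04 (adjusted p = 0.0042; adjusted p = 0.341 with an estimated correlation), and 3 of 20 members rose (3 adjusted over the list alone). These were Cyp3a11, the ethanol-oxidising Cyp2e1 (1.29-fold) and Pck1, which gluconeogenesis requires (1.53-fold, adjusted p = 0.0441). The call of Pck1 was lost without any one of 14 mice (32, 33, 34, 35, 36, 38, 71, 73, 75, 76, 77, 78, 79 and 80; adjusted p up to 0.0880). The 14 hepatocyte genes that no other list holds differed by 0.04 ± 0.04 (permutation p = 0.245, adjusted p = 0.407).

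Immediate early genes, transcription factors and their partners that cells switch on within minutes of a stimulus, were higher in BLT1i livers by 0.61 ± 0.10 (SE, n = 10 per group; 95% confidence interval 0.41 to 0.81; permutation test, adjusted p = 0.00049). With an estimated correlation in camera the adjusted p was 0.0444. All 10 BLT1i mice lay above every CDAA-HFD mouse. Of the 18 members 11 rose and none fell (12 higher and 1 lower adjusted over the list alone). Egr1 rose 2.82-fold (167 ± 64.6 to 471 ± 89.6 CPM), Jun 1.64-fold and Zfp36 1.68-fold, whereas the heat shock genes of the list, Hspa1a, Hspa1b and Hsph1, gave -0.25 ± 0.10, -0.07 ± 0.15 and -0.09 ± 0.09. The PPAR-alpha and xenobiotic lists were higher in the same mice as a group, and the collagen list was lower. A difference between the same groups does not show a link between the lists. Of the variance of the immediate early score, 69.5% lay between the groups. With the score as a covariate, 79 of the 101 genes that passed were among the 788. Of the 788, 771 kept their sign.

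Acute phase proteins were lower, with a score difference of -0.15 ± 0.05 (SE, n = 10 per group; permutation test, adjusted p = 0.0259; adjusted p = 0.341 with an estimated correlation). All 10 BLT1i mice lay below the CDAA-HFD median. Of 25 members 4 fell and none rose (5 lower adjusted over the list alone). Saa1 fell to 0.639 of its level (80.1 ± 14.1 to 51.2 ± 4.41 CPM), Saa2 to 0.593, Lcn2 to 0.629 (406 ± 86.2 to 256 ± 44.8 CPM) and Saa3 by 0.38 on the log2 scale. C3 and Hp gave -0.03 ± 0.05 and -0.11 ± 0.07, and the fibrinogen gene Fga had 2290 ± 423 and 2287 ± 120 CPM. The list's call was lost without CDAA-HFD mouse 39 or BLT1i mouse 72 (adjusted p up to 0.0558), and without the members that another list holds (adjusted p = 0.0524). Unfolded protein and integrated stress response genes were higher by 0.17 ± 0.07 (adjusted p = 0.0346; adjusted p = 0.713 with an estimated correlation), but BLT1i mouse 72 stood apart, and without it the difference was 0.10 (adjusted p = 0.0727). The members went both ways, 4 of 22 higher and 2 lower (8 and 6 adjusted over the list alone). The stress hormones Gdf15 and Fgf21 rose 2.69-fold and 2.37-fold and Atf3 1.43-fold, with Ppp1r15a, while the endoplasmic reticulum chaperones Hsp90b1 and Pdia4 fell by 0.22 and 0.22 on the log2 scale. Fgf21, which the PPAR-alpha list also holds, had 14.7 ± 4.25 and 34.8 ± 25.4 CPM, with 104 CPM in BLT1i mouse 72. Its call held without each mouse in turn (edgeR adjusted p up to 0.0374). The calls of Ppp1r15a (without any one of mice 31, 32, 33, 34, 39, 72, 73, 75, 76, 77 and 79), Hsp90b1 (31, 33, 34, 36, 74, 76, 77 and 79) and Pdia4 (31, 33, 34, 39, 71, 74, 76, 77, 79 and 80) were lost, with adjusted p up to 0.0767, 0.0704 and 0.0794. The call of this list was lost without any one of mice 32, 33, 36, 39, 40, 71, 72, 73 and 78 (adjusted p up to 0.0727) and with library totals alone (adjusted p = 0.114). Without the members that another list holds its score differed by 0.02 (adjusted p = 0.925). The p53 and senescence list was higher by 0.14 ± 0.04 (adjusted p = 0.0158; adjusted p = 0.601 with an estimated correlation), with a median log2 fold change of 0.02. Gdf15 and the cyclin Ccnd1 (1.21-fold) were among the members that rose and Phlda3 fell, while the p53 targets Cdkn1a and Mdm2 gave -0.19 ± 0.15 and 0.03 ± 0.04. Adjusted over the list alone, 4 were higher and 1 lower of 18. Without the members that another list holds, such as Gdf15, the adjusted p of the p53 and senescence genes was 0.944.

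**Figure D3:**
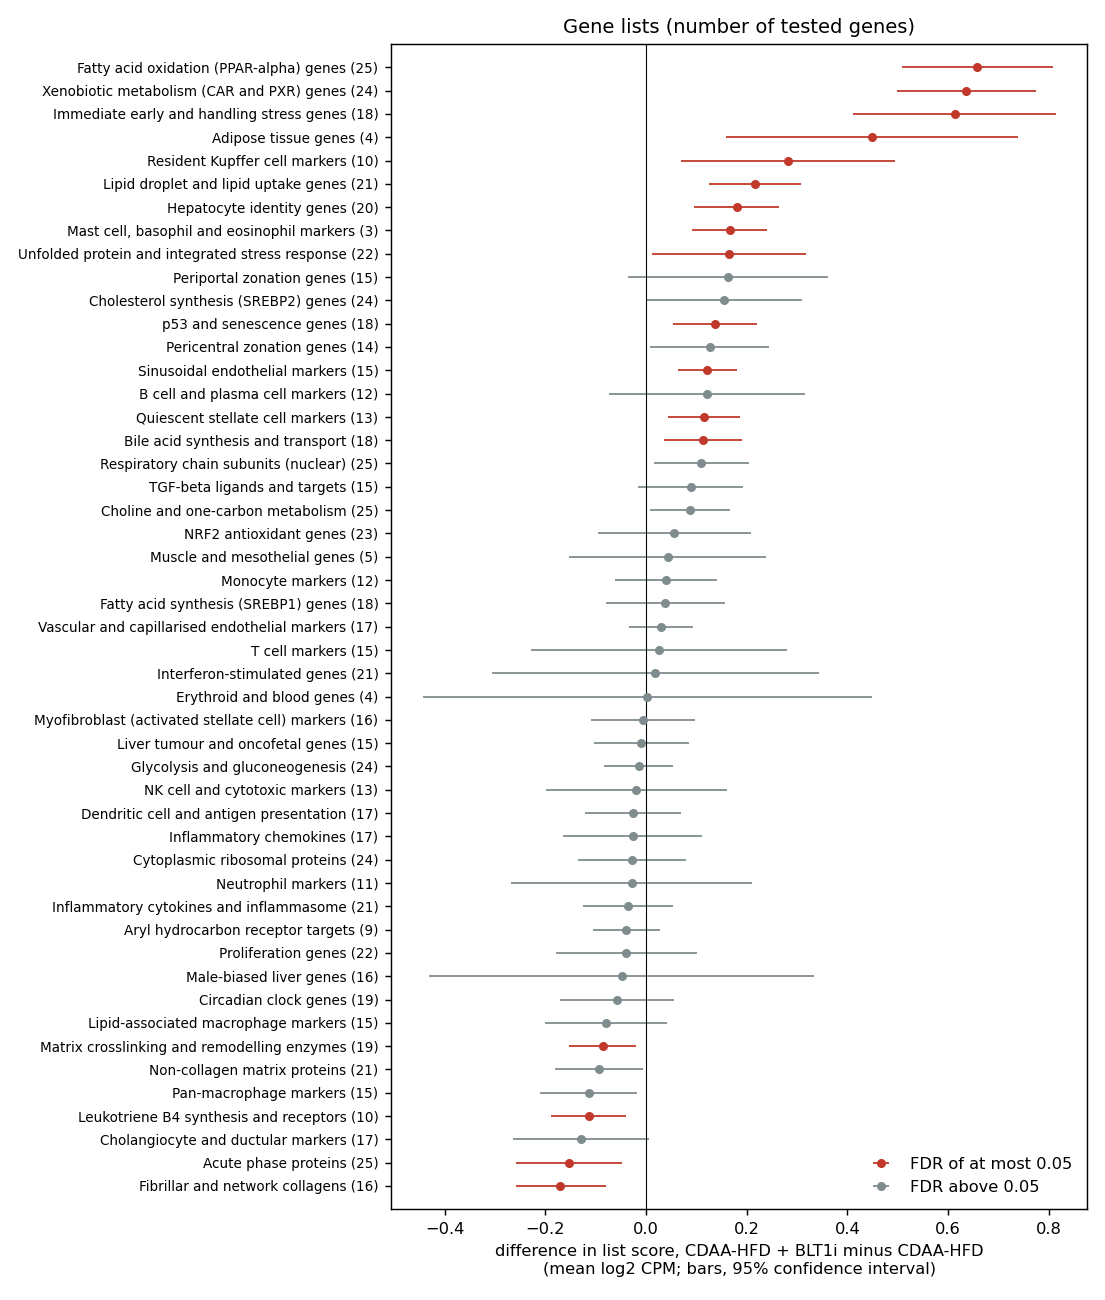
Difference in list score (mean log2 CPM of BLT1i mice minus CDAA-HFD mice, n = 10 per group) for the 49 tested lists, with the number of tested genes in brackets; bars are 95% confidence intervals and red points passed the permutation test after adjustment. The differences run from -0.17 for collagens to 0.66 for PPAR-alpha genes, and 17 lists passed, 13 higher and 4 lower.

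Over the 49 lists tested, 13 were higher and 4 lower with BLT1i (permutation test over mice, 100000 resamples, two-sided, adjusted over lists). The count was 11 without BLT1i mouse 72, 11 without mice 36 and 72 and 11 without members that more than 1 list holds (both chosen after seeing the data). Without mice 36 and 72 the leukotriene, matrix crosslinking, Kupffer, acute phase, stress response and adipose lists lost their calls. With z scores the Kupffer, hepatocyte, acute phase, stress response and p53 lists did, and with fry the Kupffer, stress response and p53 lists. The count was 3 with an estimated correlation in camera, the xenobiotic, PPAR-alpha and immediate early lists. The adipose tissue list was also higher, by 0.45 ± 0.14 (adjusted p = 0.0236; adjusted p = 0.177 with an estimated correlation). Of its 9 genes 4 could be tested, and the 2 that rose, Cidec and Pck1, are also made by fatty hepatocytes. Car3 gave -0.27 ± 0.09 (2 higher and 1 lower adjusted over the list alone).

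The remaining lists did not pass. Respiratory chain subunits differed by 0.11 ± 0.04 (adjusted p = 0.0614), with 4 of 25 members higher, among them Ndufs1 (1.15-fold) and the ATP synthase gene listed here as Atp5f1 (1.14-fold), and 10 higher adjusted over the list alone. Choline and one-carbon genes differed by 0.09 ± 0.04 (adjusted p = 0.0747), with 6 of 25 higher, among them Chdh, which oxidises choline (0.26 ± 0.04 on the log2 scale), and Cept1 (1.13-fold), and 9 higher adjusted over the list alone. Cholesterol synthesis genes differed by 0.16 ± 0.07 (adjusted p = 0.105), with 3 of 24 higher, among them Hsd17b7 (1.30-fold) and Stard4 (1.24-fold). The call of Stard4 was lost without any one of mice 34, 76 and 79 (adjusted p up to 0.0616). Pericentral genes (0.13 ± 0.06, adjusted p = 0.0884) included Oat (1.42-fold), and periportal genes (0.16 ± 0.09, adjusted p = 0.19) Pck1 and Aldh1b1 (0.35 ± 0.11). NRF2 targets differed by 0.06 ± 0.07 (adjusted p = 0.651), with 3 of 23 members higher and 1 lower (5 and 3 adjusted over the list alone) and Gstm3 up 1.43-fold. Glycolysis and gluconeogenesis genes differed by -0.01 ± 0.03 (adjusted p = 0.82), with 1 of 24 members higher, Pck1, and 2 lower (1 and 3 adjusted over the list alone). Pkm fell to 0.869, a call lost without any one of mice 33, 34, 39, 71 and 79 (adjusted p up to 0.0555). Male-biased genes differed by -0.05 ± 0.18 (adjusted p = 0.897, with the opposite direction in fry) and split. Cyp4a12b rose 2.53-fold and Serpina1e and Mup20 fell (3 higher and 5 lower adjusted over the list alone). The call of Mup20 was lost with limma-voom (adjusted p = 0.0546) and without mice 36 and 72 (adjusted p = 0.053). Proliferation genes (-0.04 ± 0.07, with Rrm2 at -0.26 ± 0.10 and Top2a at -0.11 ± 0.08), tumour and oncofetal genes (-0.01 ± 0.04, with Abcc4 higher and Prom1 lower) and circadian clock genes (-0.06 ± 0.05, with Hlf down to 0.833 and Npas2 at -0.44 ± 0.14) had adjusted p of 0.764, 0.897 and 0.482. Cytoplasmic ribosomal proteins (-0.03 ± 0.05, with Rps15 at -0.09 ± 0.05 and Rps23 at -0.12 ± 0.09, or -0.04 without mouse 37) had an adjusted p of 0.81. Erythroid genes (0.003 ± 0.21, median log2 fold change -0.18, with Hbb-bs at -0.61 ± 0.46, which turned to 0.06 without CDAA-HFD mouse 37, and Klf1 at -0.15 ± 0.19 and -0.03 without mouse 36) and muscle and mesothelial genes (0.04 ± 0.09, with Lrrn4 at 0.25 ± 0.22, or 0.40 without mouse 35, and Msln at -0.14 ± 0.17, or -0.08 without mouse 35) had adjusted p of 0.99 and 0.81. Pancreatic and mitochondrially encoded genes had too few tested members for a list test. Cela1 had 5.07 ± 0.881 and 6.33 ± 4.24 CPM, Cela2a 0.510 ± 0.314 and 1.78 ± 3.95 CPM and mt-Atp6 1064 ± 247 and 1177 ± 305 CPM, and none of the 3 passed. BLT1i mouse 74 made the higher means of Cela2a and Cela1, whose log2 fold changes without it were 0.06 and -0.02. That of mt-Atp6 went from 0.15 to 0.07 without CDAA-HFD mouse 39.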

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

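The tests of hepatocyte share, shared reads, fasting, handling, cell dilution and myofibroblast number, and that of single mice for the immediate early genes, were chosen after the result was seen. The tests of regrouped mice and of single mice for the collagens were not. After values were known, the test of hepatocyte share was moved from the xenobiotic to the joint score, the fasting criterion was replaced, the handling criterion was reworded, and a bound by the spread of the markers was added for hepatocyte share, dilution and myofibroblast number. Of 362 group values examined, 20 had a mouse whose gap to the nearest other mouse, divided by the range of its group, exceeded Dixon's critical value of 0.466 for 10 samples. Chance gives about 1 in 20, or 18.1 here.

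Values in this paragraph are log2 CPM, or the mean log2 CPM for lists. BLT1i mouse 72 was highest for the unfolded protein and integrated stress response list (6.352, others 5.733 ± 0.101, SD) and for Fgf21 (6.705, others 4.716 ± 0.382), and lowest for S100a8 (-0.42). BLT1i mouse 79 was highest for the PPAR-alpha list (7.899, others 7.53 ± 0.087), Vsig4 (5.689) and Cidec (6.128). BLT1i mouse 75 was highest for the immediate early list (6.442, others 6.015 ± 0.113) and lowest for Tmem28 (-0.661) and Abcb4 (9.057). BLT1i mouse 74 stood apart for the pancreatic enzymes Cela2a (3.71, the next mouse -0.17) and Cela1 (4.201, others 2.34 ± 0.162). BLT1i mouse 73 was lowest for Ccnd1 (7.914). CDAA-HFD mouse 36 was lowest for Id3 (5.272) and Rrm2 (2.941) and highest for Cyp4a12b (5.709, others 4.445 ± 0.23). CDAA-HFD mouse 37 was highest for the vascular endothelial list (3.861) and Hbb-bs (3.413). CDAA-HFD mouse 32 was lowest for lipid-associated macrophage markers (7.634, others 7.985 ± 0.072), mouse 33 highest for Thrsp (5.42, others 3.945 ± 0.325) and mouse 39 lowest for mt-Atp6 (9.088, others 10.115 ± 0.23).

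Chance assignment of mice to groups is argued against for both counts but not excluded, because only 100 splits were drawn. Of 100 splits of the 20 mice into groups of 10, 1 gave as many genes, the real one, with 788 against 274 in the highest other split. For lists, 1 of 100 gave as many, again the real one, with 17 against 8 (10000 permutations per list).

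The xenobiotic and PPAR-alpha lists rose together (joint score of 49 genes 0.65 ± 0.06, SE, n = 10 per group), and a larger share of hepatocyte RNA is argued against as the whole cause, since the joint score rose by 0.605 ± 0.049 more than 14 hepatocyte genes that no other list holds. The median log2 fold change of these 14 was 0.014 (SD 0.104), against 0.364 for the joint list. Reads shared within gene families are argued against as the whole cause for the PPAR-alpha genes. The 24 genes left without the Cyp, Ugt, Ces, Acot, Gst, Sult, Akr, Acaa1 and Aldh1a families rose by 0.374 ± 0.056. Most of these 24 were PPAR-alpha members. Most xenobiotic members belong to the families left out, so the test cannot decide this for the xenobiotic list. Fasting at collection cannot be told apart from treatment: the SREBP1 score, which fasting lowers, differed by 0.038 ± 0.056, with 5 members higher and 4 lower. A first criterion, that at least 3 members higher would argue against fasting, was met and was replaced by the score after those values were known. An action of the compound on xenobiotic receptors or PPAR-alpha may account for the rise and was not tested.

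Immediate early genes were higher in all BLT1i mice, with 10 of 10 above every CDAA-HFD mouse, which argues against a few mice as the source. Handling or time to freezing that differed between the groups cannot be told apart from treatment (difference 0.613 ± 0.096), since the order of collection is not in the labels. The heat shock members Hspa1a, Hspa1b and Hsph1 did not rise (-0.25 ± 0.10, -0.07 ± 0.15 and -0.09 ± 0.09), and heat shock was not part of the criterion. With the score as a covariate the count of changed genes was 101, while the median ratio of the log2 fold changes with to without it was 0.956 and the median SE went from 0.061 to 0.107. The covariate shares 69.5% of its variance with the group, so the lost calls could reflect that overlap as well as a real dependence.

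Collagen genes were lower as a list without any single mouse deciding it, as 0 of the 20 mice ended the call when left out, but the call was lost with an estimated correlation in camera (adjusted p = 0.165). Whether dilution by hepatocyte RNA lowered the collagens cannot be decided here, because the endothelial list was already known to be higher when the test was chosen. The sinusoidal endothelial score minus the collagen score was higher by 0.292 ± 0.06 (permutation p = 0.0002). The median log2 fold change of the endothelial markers was 0.129 (SD 0.089), against -0.148 for the collagens. Dilution alone lowers all other cell types alike, so it does not account for the gap between these lists. The endothelial markers can, however, have risen for a reason of their own. The cholangiocyte and pan-macrophage scores were lower (-0.13 ± 0.065 and -0.114 ± 0.046), so dilution as a cause of the lower collagens stays open. Fewer myofibroblasts and lower collagen mRNA per cell cannot be told apart. The myofibroblast score minus the collagen score was higher by 0.164 ± 0.059 (permutation p = 0.0117), but the myofibroblast markers went both ways, and their median of -0.011 lay above that of the collagens by 0.137, less than their SD of 0.212. Treatment, the difference the design names, stays open and was not separated from handling.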

How the results depend on the processing

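The alternatives that left out mice 36 and 72, used the immediate early score as a covariate or dropped shared list members were chosen after seeing the data. The count of genes changed by BLT1i (788) stayed within 1.5 times under other scalings, filters and tools (549 to 1107) and without each mouse (565 to 889). It was 1306 at a threshold of 0.1, 280 at 0.01 and 101 with the immediate early covariate. Higher genes (511) numbered 232 at 0.01 and 83 with the covariate. Lower genes (277) numbered 540 with library totals and 540 at 0.1, 421 with DESeq2, 184 and 181 with the rounded FPKM plus 1 and plus 0.1, 184 without a filter on these, 48 at 0.01, 18 with the covariate, and 168 to 342 without each mouse. Changed leukotriene genes numbered 2 instead of 1, by Cyp4f18, under upper-quartile scaling, library totals, DESeq2, limma-voom, 1 surrogate variable and without mice 36 and 72, and 1 to 2 without each mouse. The 17 lists became 3 with an estimated correlation, 11 without mice 36 and 72, 11 without shared members and 11 to 19 without each mouse; they were 23 with the preset correlation, 15 with fry and 13 with z scores. Under the covariate Tmem28 (0.124, adjusted p = 0.926) and Nr4a1 (-0.083, adjusted p = 0.934) changed sign. The cause was not tested for any of these, except that the thresholds change the count by construction. Nr4a1 is itself a member of the covariate score, so adjusting for the score takes out part of its own change. Genes named by the rule were run under at most 7 alternatives (RLE, DESeq2, limma-voom, the 1 CPM filter, the rounded FPKM plus 0.1, without mice 36 and 72, and the covariate). Of the 78 with a call, 20 kept it at a threshold of 0.05 under all that were run, and 65 without each mouse in turn. All 58 that lost a call lost it with the covariate, and 12 also without mice 36 and 72 (S1pr5, Col6a2, Eln, Lox, Fcer1g, Oit3, Anxa4, Pck1, Cxcl14, Casp4, Stard4 and Pkm). Col6a2 and Lox lost their calls with limma-voom, and Col6a2, Lox, Ace, Kit, Oit3, Anxa4, Pycard, Stard4 and Cept1 with the rounded FPKM. Called genes that the text names outside the rule were run under the same alternatives. Mup20 lost its call with limma-voom, Pklr with RLE, and Pklr, Ppp1r15a and Ucp2 with the rounded FPKM plus 0.1. Mup20, Ucp2 and Igfbp1 lost theirs without mice 36 and 72. With the covariate, all genes named outside the rule lost their calls but Acacb, Cpt2, Elovl5, Me1, Acsl1, Ech1, Eci1, Elovl2, Hsd17b6 and Itgam. Under an alternative, 27 values of lists, all without a call, and 13 values of genes named by the rule changed sign. The 13 include those of Tmem28 and Nr4a1, which had a call. The lane-only alternatives were not run, since the tables have 1 column per mouse. No paired analysis was possible because the groups share no mouse numbers. Depth limits genes under 1 CPM, among them Ltb4r1.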

Other observations

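The 8 relations of the collagen score were chosen after the group differences were seen and before any correlation was computed, with a criterion written for 3 of them. The genes outside the lists were chosen after their values were seen.

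Outside the lists, genes chosen after their values were seen showed further changes (edgeR log2 fold change ± SE, n = 10 per group). Hsd17b6, which oxidises androgens and retinol, rose 2.32-fold from 86.4 ± 12.4 to 201 ± 25.2 CPM (adjusted p = 1.09e-09). Ech1, Eci1 and Decr2, auxiliary enzymes for the oxidation of unsaturated fatty acids, rose by 0.47 ± 0.05, 0.41 ± 0.06 and 0.44 ± 0.07, with Acsl1 (0.55 ± 0.08) and the peroxisomal protein Pex11a (0.43 ± 0.10). Elovl2, which elongates polyunsaturated fatty acids, rose by 0.52 ± 0.05. The insulin-like growth factor binding proteins Igfbp1 and Igfbp2 rose 1.96-fold and 1.82-fold (adjusted p = 0.0319 and 9.78e-06), and the growth factor Hbegf 1.79-fold. The call of Igfbp1 was lost without mouse 72 or mouse 79 (adjusted p up to 0.0592). Ketohexokinase (Khk), the first enzyme of fructose metabolism, fell to 0.781 of its level (adjusted p = 0.00285), and Tsc22d3, a glucocorticoid-induced gene, to 0.672 (adjusted p = 0.0112).

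Several called genes outside the lists were lower in BLT1i mice. The matrix genes Fmod, Ccn5 and Col8a2 fell to 0.686, 0.634 and 0.696 of their levels (adjusted p = 0.00393, 0.00499 and 0.00992), Fmod from 33.3 ± 5.69 to 22.8 ± 4.32 CPM. The leukocyte genes Itgam, which encodes CD11b, and C5ar1, a receptor for complement C5a, fell to 0.821 and 0.801 (adjusted p = 0.0112 and 0.0134), each lower in all 10 BLT1i mice than the CDAA-HFD median. The endoplasmic reticulum proteins Calr and Pdia3 fell to 0.81 and 0.854 (adjusted p = 0.00773 and 0.0140). Saa4, a serum amyloid A gene expressed without inflammation, fell to 0.782 (adjusted p = 2.04e-05).

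Whether collagen varied with other scores within a group was examined in 8 relations (n = 10 mice each, permutation tests, adjusted over the 8). In BLT1i mice collagen and pan-macrophage scores were correlated (Pearson r = 0.897, p = 0.00048, adjusted p = 0.00384; Spearman rho = 0.842, p = 0.00386, adjusted p = 0.0309), and r was 0.734 without mice 75 and 80, the farthest from the median. In CDAA-HFD mice r was 0.397 (p = 0.256, adjusted p = 0.41; 0.53 without mice 39 and 32) and rho 0.612 (p = 0.0671, adjusted p = 0.179), and the difference between groups was not tested. A link between macrophages and collagen was not separated from variation in the amount of non-parenchymal tissue per sample. The relations of collagen with the xenobiotic score (r = -0.58, p = 0.0786, adjusted p = 0.253; rho = -0.685, p = 0.0347, adjusted p = 0.139; r = -0.761 without mice 76 and 79) did not pass in BLT1i mice. Nor did those with the PPAR-alpha score (r = -0.447, p = 0.197, adjusted p = 0.394; rho = -0.333, p = 0.348, adjusted p = 0.56), which gave r = 0.304 without mice 79 and 75. The criterion set for these, an adjusted p of 0.05 or more as evidence against a link, was too weak, because 10 mice can miss a correlation of this size, so both links stay open. The immediate early score gave r = 0.557 (p = 0.0948, adjusted p = 0.253) and rho = 0.333 (p = 0.35, adjusted p = 0.56) in BLT1i mice, and r = 0.115 without mice 75 and 77. In CDAA-HFD mice r was -0.103 for PPAR-alpha, -0.004 for xenobiotic and -0.233 for immediate early genes (p = 0.775, 0.991 and 0.525, adjusted p = 0.886, 0.991 and 0.7). The rho values were -0.115, -0.018 and -0.115 (p = 0.762, 0.973 and 0.76, adjusted p = 0.871, 0.973 and 0.871), and r without the 2 farthest mice was 0.12, -0.176 and -0.376.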
